A study of Mus musculus with 14 samples.

How the data were processed

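Liver RNA of 14 mice was labelled from 100 ng per sample with the Affymetrix WT PLUS kit and measured on whole-transcript arrays, per the labels' protocols. The deposited values are log2 expression per probe set made by RMA (background correction, quantile normalization and summary of probes), as the submitters' processing notes name RMA without a version. The summarising software, its annotation and any filter are not given in the sources used here. The table held 41345 probe sets, with array medians from 3.443 to 3.491 and near-equal quartiles. It holds no detection calls. RMA compresses differences of genes close to background, so that log2 differences of dim genes understate the change. Depth does not apply to arrays, and their number, 7 per group, limits the precision.

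Groups were taken from the sample titles and not from the values. The numbers in the titles run over both groups without a shared number, so no pairing was made. Their mean was 5.71 in the sleep-deprived and 9.29 in the control group (exact permutation test, two-sided, p = 0.128). The labels name no batch, time of day, feeding state or date of collection, and number the liver samples without stating that each came from its own mouse. Each is taken as 1 mouse here, and p-values of single genes measure the spread between these samples. The median absolute difference between a pair of arrays lay between 0.146 and 0.194, with no pair standing apart as a repeated library.

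Probe sets were named through the platform's annotation with symbols updated by Entrez gene ID: 23521 had 1 gene symbol, 1814 had several and 16010 were not listed there and are unnamed here. Of the first, 23328 were matched by ID, and the other 193 kept the annotation's symbol. The update changed 0 symbols. For a gene with several probe sets (1082 genes) the brightest over all 14 arrays was used, which left 22180 genes and no filter on dim ones. Among changed genes, 110 had several probe sets, and in 32 of these the probe sets differed in sign. No genome build is named for the table, so positions are not given.

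Sleep-deprived minus control was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided). P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The SE of a gene is limma's moderated SE, which draws the gene's spread toward that of other genes. For a gene that varies much between mice, it can be smaller than the SDs of the groups give. Gene lists, 39 in number, were fixed from textbook knowledge before the data were examined, as were the design, the alternatives and the rule for the genes named. The lists held 739 members, of which 659 were measured. They were tested with camera at a preset inter-gene correlation of 0.01, again with a correlation estimated for each list, and with fry, each adjusted over the 39 lists. Camera sets the genes of a list against the other genes. At the preset correlation its p-values do not take from these samples how the genes of a list vary together. Those p-values therefore do not measure the spread between mice. Some genes stand in more than 1 list, such as 7 of the measured members of the amino acid and of the periportal lists and 5 of the hepatocyte list. The lists covered the clock, lipid, cholesterol, bile acid, glucose, amino acid and xenobiotic metabolism, hormone and stress responses, inflammation, ribosomes, mitochondria, the cell cycle and markers of 13 cell types or zones of the liver.

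Genes were named by a rule. It took the 12 largest rises and 12 largest falls among genes past the threshold, up to 4 members per list with the smallest adjusted p, and 22 core genes whatever their result. Predicted models, clone names and small RNA genes were left out of the largest changes (93 changed genes, of which 1 had a larger rise than the last one named). Of the 22 core genes 19 were measured, and the others are not reported here. The rule gave 122 genes, 116 of them past the threshold, and not all of them are described.

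The alternatives were eBayes without the trend or with robust estimation, array weights, the brighter genes alone, the mean of a gene's probe sets, every probe set as its own feature, centring each array on its median, quantile normalization again, the sample number as a covariate, other list tests, a log2 threshold of 0.5 and leaving out each of the 14 mice. The same steps were tested on simulated data with the spread of these arrays (22180 genes, 200 of them changed). They recovered 80% of 100 genes changed by 0.5 on the log2 scale and 100% of 100 changed by 1, with 14 false calls (7.22% of calls). In a simulation of 39 lists with independent genes, the list of 20 genes shifted by 0.3 passed camera (adjusted p = 2.72e-42) and 0 of the others did.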

Results

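Gene expression was measured in the liver of 14 male C57BL/6J mice, an inbred laboratory strain, on Affymetrix whole-transcript arrays hybridised with biotin-labelled material made from 100 ng of total RNA per sample. The titles placed 7 mice in a sleep-deprived group (mice 1, 2, 3, 5, 6, 10 and 13) and 7 in a control group (mice 4, 7, 8, 9, 11, 12 and 14). The study asked how a single sleep deprivation of 6 h acts on glucose tolerance and fat in the liver. Its design text names cage changing, a water platform and gentle handling as ways of disturbing sleep, and the labels do not say which of them preceded these arrays. Values were log2 expression per probe set. The median of an array lay between 3.443 and 3.491, and the correlation between any pair of arrays lay between 0.984 and 0.9903. The labels give each sample its own number, and each is taken here as 1 mouse. The number of arrays limits the precision of each value.

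The livers of the sleep-deprived mice differed from those of the controls at 1886 of 22180 genes (8.5%), of which 861 were higher and 1025 lower (limma, adjusted p under 0.05). More genes being lower did not hold with the sample number as a covariate (950 higher, 911 lower). Most differences were small. Among the 1886 genes, 1618 differed by less than 1.5-fold, while 32 were higher and 21 lower by at least 1 on the log2 scale. With the sample number as a covariate, 49 genes were higher and 24 lower by that much. The values of the groups did not overlap at 681 of the 1886 genes, and at 695 of all genes tested, where chance alone would give 12.9 (0.0583% of them). The first principal component over genes, with 23.95% of the variance, placed the 7 sleep-deprived mice apart from the 7 controls.

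**Figure D1:**
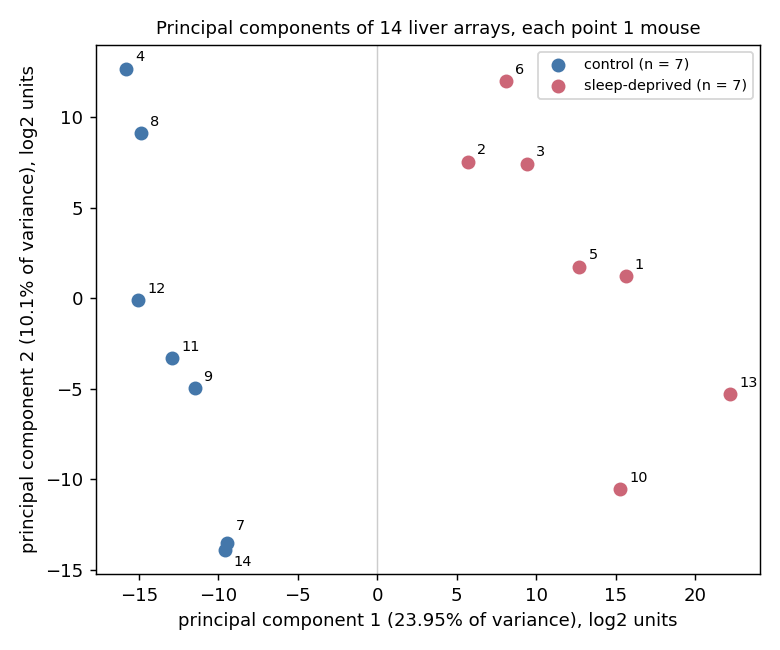
Principal components 1 and 2 (log2 units, with the percentage of variance of each) of the 14 liver arrays over 22180 genes, 1 point per mouse labelled with its number in the sample titles. All 7 sleep-deprived mice lie above 0 on component 1, at 5.69 to 22.2, and all 7 controls lie below 0, at -15.8 to -9.44.

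Cdkn1a, which encodes the cell cycle inhibitor p21, had the largest rise (probe set 17335467). Its log2 level was 5.00 ± 0.23 in controls and 8.43 ± 1.19 after sleep deprivation (mean ± SD, n = 7 each). The log2 difference was 3.43 ± 0.36 (moderated SE, as for the single genes below) or 10.8-fold (limma, adjusted p = 4.47e-06). Cyp4a14, a fatty acid omega-hydroxylase (probe set 17428457), rose by 2.91 ± 0.62 (limma, adjusted p = 0.00439), and Cyp2b10, a drug-metabolising cytochrome P450 (probe set 17475360), by 2.37 ± 0.37 (limma, adjusted p = 0.000241). The other 9 genes with the largest rises were Fam107a (2.20), Ddit4 (2.10), Ppp1r3c (1.94), Cyp17a1 (1.69), Lpin1 (1.57), Fkbp5 (1.55), Plin5 (1.54), Igfbp1 (1.45) and Elovl3 (1.42). Their standard errors lay between 0.099 (Fkbp5) and 0.25 (Fam107a). The value of Fam107a was 1.17 when its 2 probe sets were averaged. In Cyp4a14, sleep-deprived mouse 2 had a log2 level of 6.81, inside the range of the controls, and each of the other 11 genes was above the control mean in all 7 sleep-deprived mice.

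The largest falls were those of Clec2h, a C-type lectin gene (probe set 17463443), at a log2 difference of -1.72 ± 0.21 (limma, adjusted p = 2.36e-05), Cabcoco1 (probe set 17241676) at -1.50 ± 0.12 (adjusted p = 1.15e-07) and the desmosomal cadherin Dsg1c (probe set 17348707) at -1.49 ± 0.18 (adjusted p = 1.42e-05). Next came the guanylate-binding protein gene Gbp11 (-1.42 ± 0.43), the peroxisomal fatty acid transporter Abcd2 (-1.38), Apol7a (-1.35), Srebf1 (-1.35), the transcriptional repressor Bcl6 (-1.24), the chemokine Cxcl1 (-1.22), the receptor Erbb4 (-1.22), the sorting receptor Sort1 (-1.12) and Gsap (-1.08). The call of Gbp11 (limma, adjusted p = 0.0429) was lost in 10 of the 14 fits that left out 1 mouse, where its adjusted p reached 0.0975. A dimmer probe set of Sort1 went the other way, and the value of Sort1 was -0.53 when its probe sets were averaged.

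**Figure D2:**
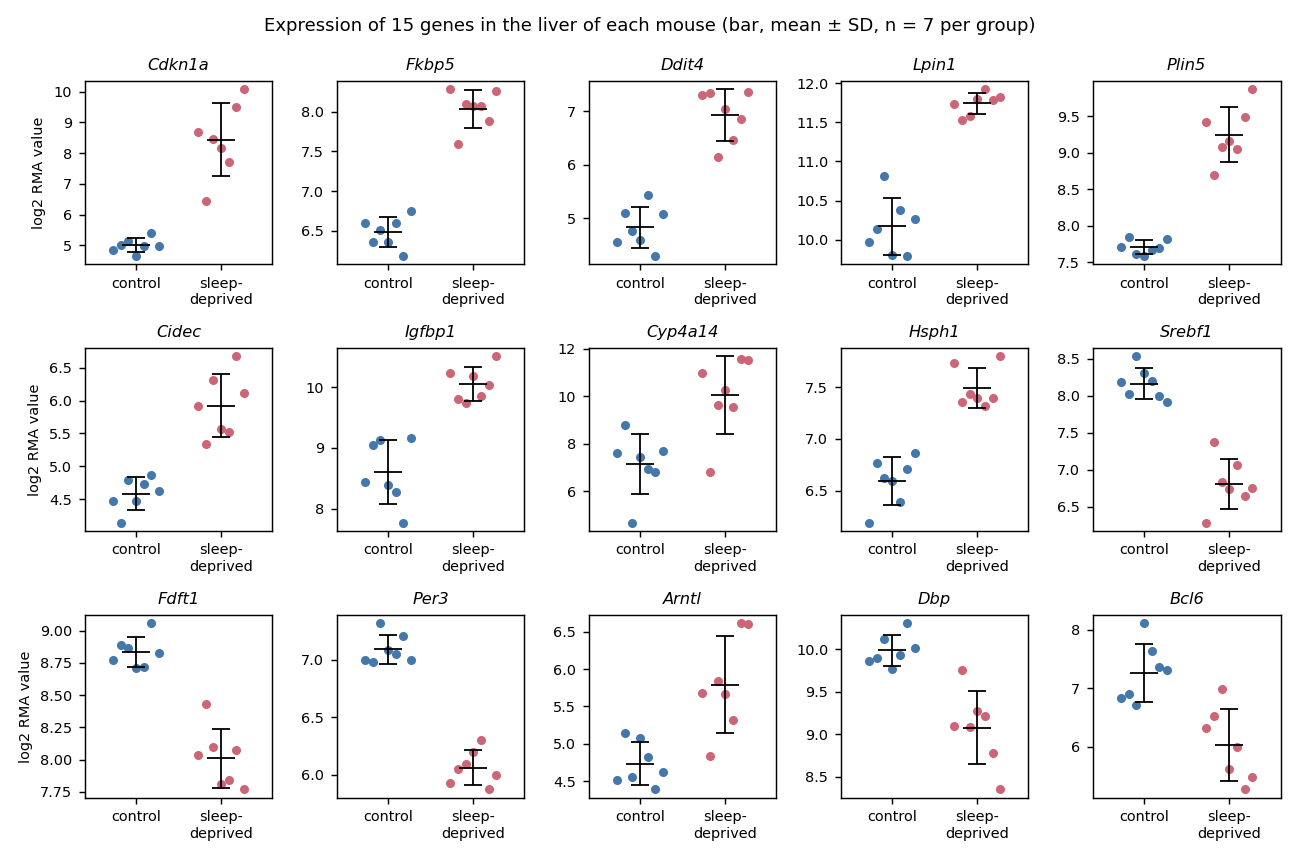
Log2 RMA value of 15 genes in each liver, 7 control mice in blue and 7 sleep-deprived mice in red, 1 point per mouse, with the mean ± SD of each group in black. In Cdkn1a, the controls centre on 5.00 and the sleep-deprived mice on 8.43, and in Srebf1 the means are 8.16 and 6.82.

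Genes known to respond to glucocorticoids, the adrenal stress hormones, rose together. Among the 20 measured, 11 were higher and 1 lower (15 and 1 adjusted over the list alone), with a median log2 difference of 0.41. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 1.55 ± 0.099, Ddit4, an inhibitor of mTORC1 signalling, by 2.10 ± 0.19, Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, by 0.62 ± 0.10 and the tyrosine-degrading enzyme Tat by 0.41 ± 0.047. Per1, also a member, was at 0.13 ± 0.096 (limma, adjusted p = 0.534). The list passed camera at a preset correlation (adjusted p = 4.20e-17) and with an estimated correlation (adjusted p = 0.0155). Of its members 4 also stand in other lists, Cdkn1a not among them.

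Heat shock proteins and genes of ribosome biogenesis were also higher. Of 17 heat shock genes 9 rose and 0 fell (13 and 0 adjusted over the list alone), among them Hsph1 (0.90 ± 0.099), the co-chaperones Chordc1 (0.60 ± 0.095) and Bag3 (0.59 ± 0.085) and the small heat shock protein gene Hspb1 (0.59 ± 0.080), which has another probe set of opposite sign (0.28 when averaged). In ribosome biogenesis 12 of 23 genes rose and 0 fell (15 and 0 adjusted over the list alone), such as Nop58 (0.57 ± 0.092), Nop56 (0.54 ± 0.074), Gnl3 (0.50 ± 0.084) and Nop16 (0.45 ± 0.050). Camera adjusted p was 5.89e-12 for heat shock proteins and 2.05e-12 for ribosome biogenesis, and 0.0155 and 0.0466 with an estimated correlation. The call of Nop56 was lost when its 3 probe sets were averaged (adjusted p = 0.0938). Of 24 genes of cytosolic ribosomal proteins, which are parts of the finished ribosome, 0 passed (2 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.282).

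The 3 lists above were the ones whose call held with an estimated correlation. With the preset correlation, 13 of 39 lists were higher and 7 lower. Fry, which tests whether the genes of a list move 1 way on balance, called 16 lists, and its mixed test, for change in either direction, 32. Calls at the preset correlation need care, since a median of 6 lists passed in 99 other splits of the same mice. Those splits kept 4 to 6 of 7 mice of a real group together, so part of the real difference may add to that number. Markers of sinusoidal endothelial and stellate cells were among the lists that were higher, by a mean of 0.18 and 0.14, beside the gene groups described here.

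**Figure D3:**
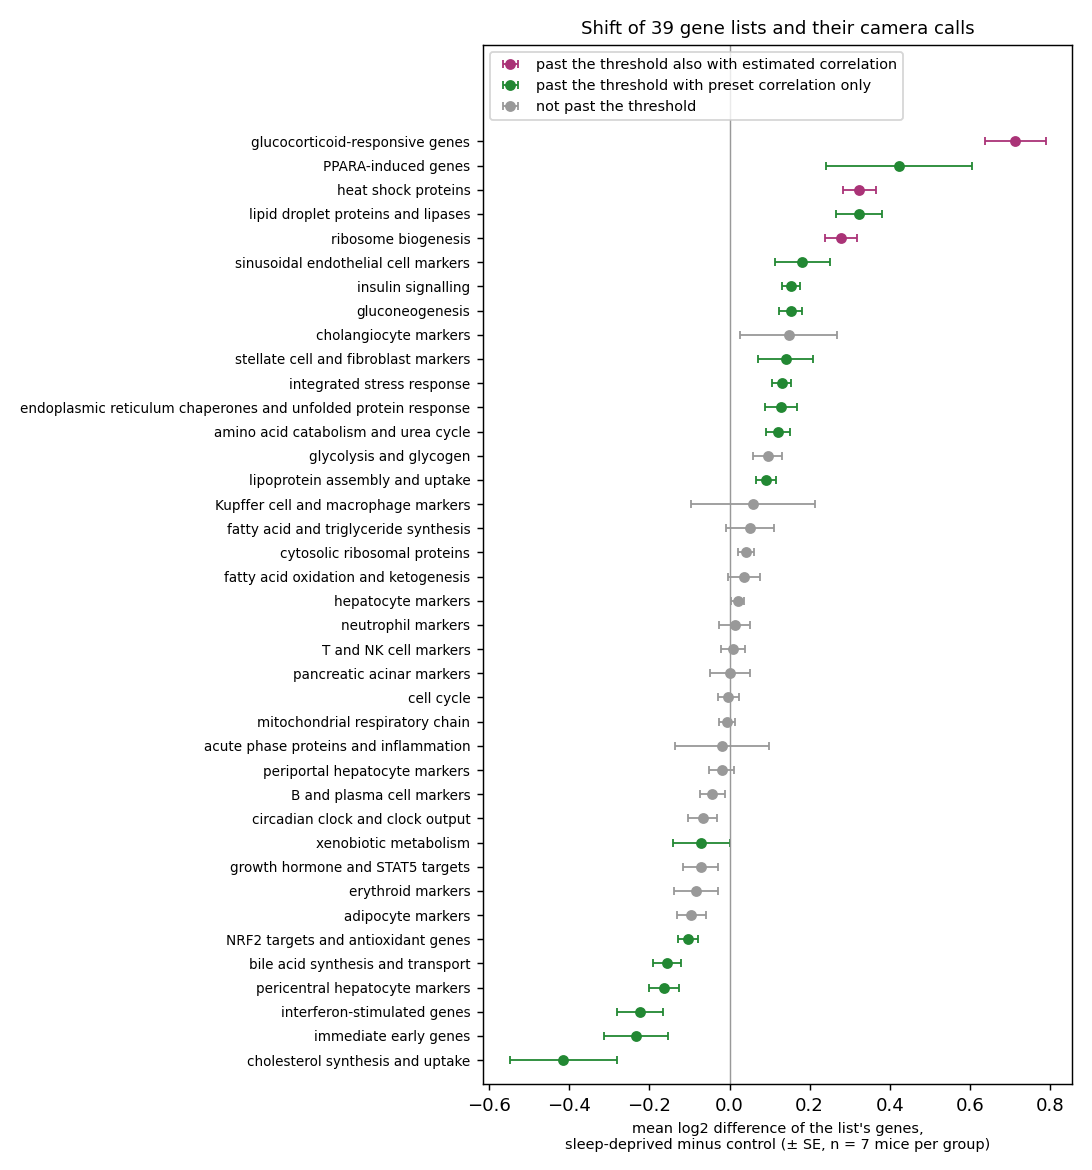
Mean log2 difference of the genes of each of 39 lists, sleep-deprived minus control, with its SE over mice (n = 7 per group) as the bar and the camera call as the colour. Glucocorticoid-responsive genes lie highest at 0.71, and cholesterol synthesis and uptake lowest at -0.41.

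Protein folding genes of the endoplasmic reticulum rose in part. Here 6 of 19 genes were higher and 0 lower (7 and 0 adjusted over the list alone), including Creld2 (0.56 ± 0.070), Hyou1 (0.43 ± 0.095), Herpud1 (0.33 ± 0.059) and Dnajc3 (0.29 ± 0.059). This gave a camera adjusted p of 0.000696, and adjusted p = 0.245 with an estimated correlation. In the integrated stress response 3 of 18 genes rose and 0 fell (3 and 0 adjusted over the list alone): the hormone gene Fgf21 (1.37 ± 0.22) and the transcription factors Atf5 (0.50 ± 0.073) and Atf4 (0.23 ± 0.055). Its camera adjusted p of 0.0290 became adjusted p = 0.123 with an estimated correlation, 0.0503 without sleep-deprived mouse 2 and 0.0647 without control mouse 12. Immediate early genes, which respond within minutes to stimuli, went down in part, with 1 of 19 higher and 4 lower (1 and 6 adjusted over the list alone). Among the lower were Fos (-0.82 ± 0.19), Junb (-0.56 ± 0.10) and the mRNA-decay factor Zfp36 (-0.33 ± 0.084, limma adjusted p = 0.0606 with every probe set tested). The 1 that rose was Klf10 (0.39 ± 0.11, adjusted p = 0.0522 without sleep-deprived mouse 5). Their camera adjusted p was 0.0176, adjusted p = 0.407 with an estimated correlation, 0.0656 without control mouse 7 and 0.0762 without control mouse 8.

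Lipid droplet genes were higher after sleep deprivation. Of 17 measured, 7 rose and 1 fell (8 and 2 adjusted over the list alone). Plin5 and Plin4, which coat lipid droplets, rose by 1.54 ± 0.12 and 1.23 ± 0.20, Cidec, which promotes droplet growth, by 1.33 ± 0.17, and Pnpla2, the lipase that starts triglyceride breakdown, by 0.46 ± 0.056. Plin2, another droplet coat protein, was at 0.16 ± 0.074 and did not pass (limma, adjusted p = 0.235). The list had a camera adjusted p of 1.86e-05, and adjusted p = 0.123 with an estimated correlation.

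Genes induced by PPARA, the nuclear receptor of fasting, rose in part, 5 of 18 being higher and 1 lower (8 and 2 adjusted over the list alone). Beside Cyp4a14 these were led by Fgf21 (1.37 ± 0.22), the acyl-CoA thioesterase Acot1 (1.33 ± 0.26) and the lipase inhibitor Angptl4 (0.67 ± 0.095). Pdk4, a kinase that restrains glucose oxidation, was at 0.70 ± 0.27 and did not pass (limma, adjusted p = 0.138), but did without sleep-deprived mouse 2 (0.0412) or mouse 6 (0.0424). The list's camera adjusted p was 0.00596, adjusted p = 0.444 with an estimated correlation and 0.0707 without sleep-deprived mouse 10. In fatty acid oxidation and ketogenesis 1 of 19 genes was higher and 2 lower (7 and 3 adjusted over the list alone, camera adjusted p = 0.282), the isomerase Eci2 at 0.27 ± 0.064 and the dehydrogenases Bdh1 and Hadh at -0.41 ± 0.071 and -0.21 ± 0.043. Cpt1a, which admits fatty acids to mitochondria, was at 0.066 ± 0.034 (limma, adjusted p = 0.304).

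Fatty acid and triglyceride synthesis genes moved in both directions, 4 of 24 up and 4 down (4 and 5 adjusted over the list alone). Lpin1 and Lpin2, phosphatidate phosphatases of triglyceride synthesis, rose by 1.57 ± 0.12 and 0.47 ± 0.073, and the fatty acid elongase Elovl3 by 1.42 ± 0.16. Srebf1, the transcription factor that drives lipogenic genes, had a log2 difference of -1.35 ± 0.13 (limma, adjusted p = 1.15e-06). Fasn, the fatty acid synthase, was at -0.090 ± 0.16 (limma, adjusted p = 0.847) and the desaturase Scd1 at 0.024 ± 0.061 (adjusted p = 0.897). As a list they did not pass camera (adjusted p = 0.954), which pointed up while the median was -0.016 and the mean 0.052, whereas fry's mixed test gave an adjusted p of 1.82e-10.

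Cholesterol synthesis and uptake genes fell. Of 19 measured, 0 were higher and 9 lower (0 and 12 adjusted over the list alone), with a median of -0.37. Fdft1, the squalene synthase, was at -0.83 ± 0.086 (limma, adjusted p = 3.78e-06), Insig1, which holds sterol regulators in the endoplasmic reticulum, at -0.79 ± 0.091, the sterol carrier Stard4 at -0.75 ± 0.13 and the sterol desaturase Sc5d at -0.65 ± 0.064. The members varied together between mice, with an estimated correlation of 0.622, so that camera's adjusted p of 1.53e-08 became adjusted p = 0.245 with an estimated correlation. In lipoprotein assembly and uptake 3 of 17 genes rose and 0 fell (5 and 1 adjusted over the list alone), among them Apoa4 (0.78 ± 0.14) and Mttp (0.28 ± 0.051), which loads lipid onto apolipoprotein B. Its camera adjusted p was 0.0356, adjusted p = 0.171 with an estimated correlation, 0.0572 without control mouse 4, 0.0816 without control mouse 7 and 0.0591 without sleep-deprived mouse 10.

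Gluconeogenesis genes rose, 7 of 14 being higher and 1 lower (7 and 3 adjusted over the list alone). The aspartate aminotransferase Got1 rose by 0.60 ± 0.079, G6pc, the glucose-6-phosphatase that releases glucose, by 0.55 ± 0.12, and Foxo1, a transcription factor inhibited by insulin, by 0.28 ± 0.060. The glycerol channel Aqp9 was at -0.33 ± 0.065. Pck1, the enzyme phosphoenolpyruvate carboxykinase, rose by 0.15 ± 0.044 (limma, adjusted p = 0.0383), a call lost in 9 of the 14 fits that left out 1 mouse, with adjusted p up to 0.0906. As a list they passed camera with an adjusted p of 0.000585, and adjusted p = 0.123 with an estimated correlation.

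In glycolysis and glycogen metabolism 4 of 15 genes were higher and 5 lower (4 and 6 adjusted over the list alone). Ppp1r3c and Ppp1r3b, which target protein phosphatase 1 to glycogen, rose by 1.94 ± 0.17 and 0.64 ± 0.097. Phka2, a subunit of phosphorylase kinase, and the glycogen branching enzyme Gbe1 were at -0.55 ± 0.060 and -0.27 ± 0.050. Camera did not call the list (adjusted p = 0.490) and pointed down, as did the median of -0.068, while the mean was 0.094. Insulin signalling had 3 of 19 genes higher and 1 lower (3 and 1 adjusted over the list alone), with Igfbp1, a binding protein of insulin-like growth factors whose transcription insulin represses, up by 1.45 ± 0.18 and Socs2, an inhibitor of cytokine signalling, by 0.73 ± 0.15. Its camera adjusted p was 0.0260, and adjusted p = 0.123 with an estimated correlation. Since insulin represses members such as Igfbp1, the direction of this list does not measure the strength of insulin signalling. The lower gene was Socs3 (-0.31 ± 0.096), whose call was lost in 11 of the 14 fits that left out 1 mouse (limma, adjusted p up to 0.101).

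Clock genes changed in both directions, 2 of 18 up and 6 down (4 and 7 adjusted over the list alone). Arntl, which encodes the clock activator BMAL1, rose by 1.06 ± 0.22 (limma, adjusted p = 0.00323) and the repressor Nfil3 by 0.44 ± 0.094. Per3 was at -1.03 ± 0.073 (adjusted p = 9.72e-08), the clock output factor Dbp at -0.91 ± 0.14 and Nr1d1, which encodes the repressor REV-ERB alpha, at -0.67 ± 0.15. The list did not pass camera (adjusted p = 0.298) and passed fry in the downward direction (adjusted p = 0.0188) and in the mixed test (adjusted p = 1.13e-08).

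Bile acid synthesis and transport genes fell, 0 of 17 being higher and 7 lower (2 and 8 adjusted over the list alone). The sterol transporter pair Abcg5 and Abcg8 was at -0.67 ± 0.089 and -0.58 ± 0.076, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at -0.60 ± 0.15 (limma, adjusted p = 0.0148, lost with robust eBayes at 0.0617 and with every probe set tested at 0.0593). For the list, camera gave an adjusted p of 0.00134, and adjusted p = 0.171 with an estimated correlation. NRF2 targets and antioxidant genes had 0 of 15 higher and 4 lower (0 and 4 adjusted over the list alone), led by Gclm and Gclc, the subunits of the enzyme that limits glutathione synthesis, at -0.32 ± 0.049 and -0.59 ± 0.094. The other lower genes, Gpx1 (-0.11 ± 0.033) and Nqo1 (-0.38 ± 0.12), lost their calls in 12 and 11 of the 14 fits that left out 1 mouse, with adjusted p up to 0.103 and 0.105. The list's camera adjusted p was 0.00487, and adjusted p = 0.123 with an estimated correlation.

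Among amino acid catabolism and urea cycle genes 8 of 18 were higher and 2 lower (9 and 4 adjusted over the list alone), including the glycine decarboxylase Gldc (0.85 ± 0.11) and the urea cycle enzyme Asl (0.38 ± 0.052), against the histidase Hal (-0.40 ± 0.062). Camera adjusted p was 0.00391, and adjusted p = 0.245 with an estimated correlation. Xenobiotic metabolism genes split, 2 of 22 being higher and 5 lower (3 and 8 adjusted over the list alone). Cyp2b10 and the sulfotransferase Sult1d1 (0.85 ± 0.067) rose, and Cyp2a4 and Cyp2a5 were at -0.87 ± 0.10 and -0.82 ± 0.14. The list's camera adjusted p was 0.0426, adjusted p = 0.444 with an estimated correlation, and over the threshold in 8 of the 14 fits that left out 1 mouse, with adjusted p up to 0.160.

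Interferon-stimulated genes fell, 0 of 15 being higher and 5 lower (0 and 6 adjusted over the list alone), such as Irf1 (-0.43 ± 0.091), Ifit1 (-0.57 ± 0.15), Mx1 (-0.35 ± 0.090) and Oasl1 (-0.37 ± 0.095). The log2 level of Mx1, 2.55 in controls and 2.20 after sleep deprivation, was close to the lower quartile of the arrays. It is not shown to lie above background. The calls of Ifit1 and Mx1 were lost with the sample number as a covariate (limma, adjusted p = 0.0980 and 0.0930), and those of Ifit1 and Oasl1 with every probe set tested (0.0702 and 0.0554). The whole list had a camera adjusted p of 0.000141, and adjusted p = 0.139 with an estimated correlation. Acute phase and inflammation genes did not pass as a list (camera adjusted p = 0.418), with 4 of 25 higher and 2 lower (5 and 3 adjusted over the list alone), among them the interleukin-1 receptor Il1r1 (0.64 ± 0.11) and the lipopolysaccharide-binding protein Lbp (0.42 ± 0.093), against Cxcl1. The other lower gene was Socs3 (-0.31 ± 0.096), whose call was lost in 11 of the 14 fits that left out 1 mouse (limma, adjusted p up to 0.101). Camera pointed up for the acute phase list, while its mean was -0.020, with either sign across settings (-0.065 to 0.055, and 0.045 without control mouse 8). Growth hormone and STAT5 targets had 1 of 18 higher and 4 lower (1 and 4 adjusted over the list alone). The higher gene was Socs2 (0.73 ± 0.15), and Bcl6 and the growth hormone receptor Ghr (-0.43 ± 0.052) were among the lower. The list did not pass (camera adjusted p = 0.128), but did without control mouse 11 (0.0321). As it also holds genes of the pathway itself, such as Ghr, its direction does not measure STAT5 activity.

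Few genes changed in the cell cycle list (1 of 20 higher, 0 lower, 1 and 0 adjusted over the list alone, camera adjusted p = 0.946) and 0 of 22 in the mitochondrial respiratory chain (5 at an unadjusted p under 0.05 in limma, 0 adjusted over the list alone, camera adjusted p = 0.621). The changed cell cycle gene was Rrm2, a subunit of ribonucleotide reductase, at 0.50 ± 0.090, with another probe set of opposite sign (adjusted p = 0.0806 when both were averaged). Camera pointed up for the cell cycle list, while its median was -0.011 and its mean -0.0029.

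Among cell type markers, those of sinusoidal endothelial cells, which line the blood vessels of the liver lobule, were higher, with 4 of 16 up and 0 down (5 and 1 adjusted over the list alone). Lyve1, a hyaluronan receptor, rose by 1.13 ± 0.18 (limma, adjusted p = 0.000422) and Oit3 by 0.46 ± 0.094. Pecam1 (0.29 ± 0.080) and Mrc1 (0.26 ± 0.080) also passed, calls lost in 6 and 9 of the 14 fits that left out 1 mouse, with adjusted p up to 0.0594 and 0.0986. Together the markers gave a camera adjusted p of 0.00123, and adjusted p = 0.435 with an estimated correlation. Stellate cell and fibroblast markers had 1 of 16 higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.00768, adjusted p = 0.407 with an estimated correlation). The gene was the pericyte gene Rgs5 (0.30 ± 0.084), lost in 8 of those fits with adjusted p up to 0.0776. Kupffer cell and macrophage markers did not pass (1 of 16 higher, 0 lower, 1 and 0 adjusted over the list alone, camera adjusted p = 0.418), but did without control mouse 12 (0.00402). Their changed member was the haemoglobin scavenger receptor Cd163 (0.88 ± 0.14).

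Pericentral hepatocyte markers, of cells around the central vein, fell, with 0 of 15 higher and 4 lower (1 and 6 adjusted over the list alone), among them Lgr5 (-1.05 ± 0.14, and -0.57 when its 2 probe sets were averaged), Lect2 (-0.44 ± 0.059) and Rgn (-0.24 ± 0.034). Camera adjusted p was 0.00391, and adjusted p = 0.195 with an estimated correlation. General hepatocyte markers (2 of 13 higher, 0 lower, 3 and 2 adjusted over the list alone, camera adjusted p = 0.437) and periportal hepatocyte markers (2 of 13 higher, 1 lower, 2 and 1 adjusted over the list alone, adjusted p = 0.781) did not pass. The higher hepatocyte markers were Apoa1 (0.12 ± 0.034) and Cps1 (0.11 ± 0.034), calls lost in 4 and 10 of the 14 fits that left out 1 mouse, with adjusted p up to 0.0681 and 0.0949. Camera pointed up for the periportal list, while its mean was -0.024.

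The remaining cell type lists did not pass camera. Their markers were dim, with mean log2 levels in controls from 2.812 (neutrophil) to 4.007 (B and plasma cell), where the median over all genes was 3.986. A lack of calls here does not show that these cells did not change. Camera adjusted p was 0.180 for cholangiocyte markers (1 of 10 higher, 0 lower), 0.849 for T and NK cell markers (0 of 15 changed, 2 at an unadjusted p under 0.05 in limma), 0.621 for B and plasma cell markers (0 of 11 higher, 1 lower) and 0.763 for neutrophil markers (0 of 16 changed, 0 at an unadjusted p under 0.05). It was 0.610 for erythroid markers (0 of 5 higher, 1 lower), 0.849 for adipocyte markers (0 of 10 higher, 1 lower) and 0.849 for pancreatic acinar markers (0 of 11 changed, 0 at an unadjusted p under 0.05). The changed genes were the biliary transcription factor Sox9 of the cholangiocyte list (0.56 ± 0.16, lost in 7 of the 14 fits that left out 1 mouse, adjusted p up to 0.0812), Cd79a of the B cell list (-0.38 ± 0.091), Klf1 of the erythroid list (-0.50 ± 0.097) and Pparg of the adipocyte list (-1.02 ± 0.17), a nuclear receptor that hepatocytes also express. Adjusted over the list alone, the numbers higher and lower were 1 and 0 for cholangiocyte, 1 and 1 for B and plasma cell, 0 and 1 for erythroid and 0 and 2 for adipocyte markers, and 0 for the others. The median was above 0 and the mean below 0 for adipocyte markers, and the reverse for pancreatic acinar markers.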

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

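The tests of the sinusoidal endothelial list, alone and against other lists, of Lyve1 and of the cholesterol list, and the counts of splits for lists and for large changes, were chosen only after the results were seen. The counts of splits and the sample number for all changed genes were set beforehand.

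The number of changed genes was weighed first. Of 100 splits of the 14 mice into 7 and 7, drawn from 1716, 1 (the real one) gave as many genes as the 1886 found, and the highest other gave 360, in a split that kept 6 of 7 mice of a real group together. Within the splits drawn, chance is unlikely for this count, and likewise for the 53 genes that differed by at least 1 on the log2 scale (1 of 100 splits, highest other 18). With the sample number as a covariate 1861 genes passed and 0 genes were associated with the number, which argues against it as the whole cause. Sleep deprivation, with whatever handling went with it, and any batch, feeding or time of collection that goes with the groups stay open and may each contribute, since the labels do not separate them.

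The 20 called lists exceeded every other split (1 of 100 splits gave as many, highest other 16). Even so, 95 of the 99 other splits gave at least 1 list and their median was 6. Chance is thus unlikely for the total, within the 100 splits drawn, but cannot be excluded for a single call at the preset correlation.

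Markers of sinusoidal endothelial cells rose by a mean of 0.18 (exact permutation test, two-sided, p = 0.0198), but camera with an estimated correlation (adjusted p = 0.435) and fry (0.101) did not call the list. A lower share of hepatocytes would raise markers of other cell types alike. General hepatocyte markers did not fall (mean 0.022, camera adjusted p = 0.437), which alone does not decide on a lower share of hepatocytes. The Kupffer cell list was at 0.058 (exact permutation p = 0.737) and the difference between these shifts was 0.12 (exact permutation p = 0.403), so this explanation cannot be told apart from a change in the endothelial cells. Without control mouse 12, which was high in Kupffer cell and macrophage markers, that list was at 0.18 (camera adjusted p = 0.00402) and the sinusoidal list at 0.20. Stellate cell and fibroblast markers were higher by 0.14 over all mice (exact permutation p = 0.0618). Over all mice, the means of T and NK cell (0.0092), neutrophil (0.014), B and plasma cell (-0.042) and erythroid markers (-0.083) did not rise alike. Control mouse 12, kept here, was also the highest control in the first 3 of these lists. Their control scores were 3.208, 2.812, 4.007 and 3.455, near or below the median level of all genes (3.986). A rise of such dim markers may be compressed, so their means do not decide the question. Of the differences between the sinusoidal list and 7 lists of other cells, that from B and plasma cell markers passed (0.22, exact permutation adjusted p = 0.0367), and the others did not (0.0816 for T and NK cell and for erythroid, 0.101 for neutrophil, 0.564 for Kupffer cell and for stellate cell, 0.794 for cholangiocyte markers). The B and plasma cell list goes against a lower share of hepatocytes, but its control score of 4.01 was close to the median gene level. The Kupffer and stellate cell lists stood at 5.60 and 6.09, although levels of different probe sets compare only roughly. Whether the B and plasma cell markers were too dim to show a rise was not tested, so a lower share of hepatocytes stays open. More endothelial cells alone would raise all their markers by about as much as Lyve1. The largest value among the other markers was 0.46 (Oit3), below Lyve1 by 0.67 ± 0.21 (SE of the difference). This SE takes the genes as independent, although both were measured in the same mice. The gap argues against more endothelial cells as the whole cause of the rise of Lyve1, which was picked as the largest of the list. What else raised Lyve1 was not tested.

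The fall of cholesterol synthesis and uptake genes was weighed against a few mice carrying it. The list's score differed by -0.41 (exact permutation test, two-sided, p = 0.0146), and the largest p on leaving out 1 mouse was 0.028, without control mouse 12. This argues against dependence on a single mouse. It does not settle whether the genes moved more than other genes whose levels vary together between mice, which the camera result with an estimated correlation (adjusted p = 0.245) leaves open.

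Single mice far from the rest of their group were sought in 322 groups of 7 values (122 genes and 39 lists in both groups), and 22 were found (6.83%), where chance gives about 1 in 20 groups (16.1). Sleep-deprived mouse 2 was low in Abcg5 (log2 7.90, the others 8.19 to 8.38), Cyp4a14 (6.81, the others 9.56 to 11.6) and Got1 (10.7, the others 11.1 to 11.3), and high in pancreatic acinar markers (3.24, the others 2.95 to 3.07). Sleep-deprived mouse 13 was low in Aqp9 (9.38, the others 9.63 to 9.81) and high in the biliary transcription factor Sox9 (7.11, the others 5.88 to 6.08) and in acute phase proteins (8.95, the others 8.59 to 8.73). Sleep-deprived mouse 10 was low in immediate early genes (5.66, the others 5.83 to 5.93) and B and plasma cell markers (3.88, the others 3.96 to 4.00) and high in cholangiocyte markers (4.37, the others 3.44 to 3.81). Sleep-deprived mouse 6 was low in Bag3 (7.52, the others 7.89 to 8.03) and stellate cell markers (5.96, the others 6.22 to 6.37), and sleep-deprived mouse 1 in Ifit1 (4.63, the others 5.22 to 5.58).

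Among controls, mouse 12 was high in Kupffer cell and macrophage markers (6.34, the others 5.26 to 5.68), neutrophil markers (2.94, the others 2.76 to 2.81) and Bdh1 (7.76, the others 7.60 to 7.66). Control mouse 11 was high in Cyp2a5 (5.60, the others 4.60 to 4.94) and low in growth hormone and STAT5 targets (8.44, the others 8.62 to 8.70). Control mouse 8 was high in Gsap (7.53, the others 7.29 to 7.39) and low in PPARA-induced genes (7.35, the others 7.79 to 8.11). Control mouse 7 was high in Hspb1 (5.16, the others 4.71 to 4.90), and control mouse 9 low in Nop16 (6.70, the others 6.82 to 6.86).

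Probe sets outside the named genes also differed between the groups when every probe set was tested with limma. Of 16010 probe sets with no gene listed 154 passed (85 higher, 69 lower), and of 1814 with several genes 58 passed (26 higher, 32 lower).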

How the results depend on the processing

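Under the alternatives other than leaving out a mouse, the number of changed genes lay between 1557 (every probe set) and 2259 (brighter genes alone, where fewer genes were tested). The sample number as a covariate gave 1861 genes, 1539 of them shared with the 1886, and more of them were higher (950) than lower (911). Leaving out 1 mouse gave 1541 (without sleep-deprived mouse 13) to 1893 genes. Of 116 named genes past the threshold 96 passed in every setting, 12 were lost in at least 1 fit without a mouse and 8 under other settings alone. Of 20 lists 14 passed in every setting with the same test. With the sample number as a covariate, 49 genes in place of 32 were higher by at least 1. A threshold of 0.5 gave 186 higher and 205 lower, by its construction. Camera with an estimated correlation called 3 lists higher and 0 lower, in place of 13 and 7, and camera on ranks called 8 higher. The cause was not tested for the covariate and the ranks.

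Among brighter genes alone, both the list members and the genes they are set against are fewer, and which of these mattered was not tested. There the lists of insulin signalling, lipoprotein assembly and uptake, integrated stress response, immediate early genes and xenobiotic metabolism lost their call (camera adjusted p = 0.0778, 0.0778, 0.0753, 0.0502 and 0.186). Fry did not call PPARA-induced genes (0.193), immediate early genes (0.101), xenobiotic metabolism (0.171), sinusoidal endothelial cell markers (0.101) or stellate cell and fibroblast markers (0.137). Camera on ranks did not call PPARA-induced genes (0.0875), lipoprotein assembly and uptake (0.137), insulin signalling (0.0562), integrated stress response (0.134), bile acid synthesis and transport (0.0562) or amino acid catabolism and urea cycle (0.182). With the sample number, integrated stress response (0.0669) and xenobiotic metabolism (0.189) were lost, while growth hormone and STAT5 targets (0.0452), Kupffer cell and macrophage markers (0.0170), cholangiocyte markers (0.0136) and the gene Pdk4 (0.00874) passed. Without the intensity trend, lipoprotein assembly and uptake (0.0678) and xenobiotic metabolism (0.0516) were lost.

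Reversed directions were seen for results near 0 that passed neither camera nor fry's directional test, or limma for single genes, and the cause was not tested. Fry's mixed test, which ignores direction, did call fatty acid and triglyceride synthesis (1.82e-10), cell cycle (0.000745), adipocyte markers (0.000421) and periportal hepatocyte markers (4.20e-08). The mean of fatty acid and triglyceride synthesis (0.052), for which camera turned down, was 0.056 for brighter genes, 0.053 for mean probe sets, 0.052 for every probe set and on ranks, 0.037 with the sample number and 0.030 to 0.081 without 1 mouse. The mean of the cell cycle list, for which camera also turned down, was -0.019, -0.016, -0.0029 and -0.0029 in these settings, -0.017 with the sample number and -0.019 to 0.013 without 1 mouse. Pancreatic acinar markers were at -0.026 with the sample number and -0.030 to 0.024 without 1 mouse, adipocyte markers at -0.095 on ranks and -0.12 to -0.073 without 1 mouse, and periportal hepatocyte markers at -0.024 with fry and -0.043 to -0.011 without 1 mouse. Without 1 mouse, T and NK cell markers ranged from -0.010 to 0.033, Scd1 from -0.019 to 0.061 and Fasn from -0.18 to 0.049. No paired analysis was possible because the groups share no sample number. Signal close to background limits dim genes: 107 of the changed genes lay below the median level of all genes.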

Other observations

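Gene families were screened after the results were seen, by the shared start of their symbols (174 families of at least 8 genes, camera at the preset correlation). Only genes at or above the median level of all genes counted as family members, while camera set them against all genes tested. Since 107 of the changed genes lay below that level, the family p-values do not compare a family with equally bright genes. The targets of p53 and LXR tested here were listed after the gene table was seen but before their own values were looked at.

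Of the families 15 passed, 9 of them lower and 6 higher after sleep deprivation, and with an estimated correlation 2 did (Akr and Car, both lower). The higher family with the smallest camera p was Nop, with 5 of 8 genes higher and 0 lower (camera adjusted p = 1.26e-05, adjusted p = 0.168 with an estimated correlation). Its higher genes, all but Nop14, also stand in the ribosome biogenesis list above, so this family is not a separate result. The cytochrome P450 genes (Cyp) did not pass, 6 of 55 being higher and 8 lower (adjusted p = 0.359). Of the 9 lower families 4 are described here. In the aldo-keto reductases (Akr) 8 of 9 genes fell and 0 rose (camera adjusted p = 2.78e-08, adjusted p = 0.0368 with an estimated correlation), among them Akr1c6 (-0.69 ± 0.087), Akr1d1 (-0.63 ± 0.10), which reduces the steroid double bond in bile acid synthesis, and Akr1c14 (-0.38 ± 0.082). In the carbonic anhydrases (Car) 3 of 8 fell and 0 rose (camera adjusted p = 2.75e-05, adjusted p = 0.0368 with an estimated correlation), with Car3 at -0.47 ± 0.049. Carboxylesterases (Ces) had 6 of 14 lower and 0 higher (camera adjusted p = 1.94e-05, adjusted p = 0.166 with an estimated correlation), with Ces1g at -0.97 ± 0.11. In aldehyde dehydrogenases (Aldh) 6 of 15 were lower and 0 higher (camera adjusted p = 0.000167, adjusted p = 0.270 with an estimated correlation), with Aldh1a1 at -0.61 ± 0.066. The genes named here were chosen after their values were seen, and near-identical members of these families can share probes.

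A hypothesis for the rise of Cdkn1a is activation of p53, of which Cdkn1a is a well-known target. Of 18 other p53 targets measured, 2 were higher (Trp53inp1 at 0.88 and Ei24 at 0.28) and 1 lower (Dcxr at -0.27). Their median was 0.0254 ± 0.0818 against the 0.2 set beforehand, with a camera p of 0.275. This SE is taken over the genes as if independent, and does not measure the spread between mice. The mean over the list was higher by 0.0838 ± 0.0368 (SE over mice, exact permutation test, two-sided, p = 0.0484). These values argue against p53 activity as a cause that would move its targets in step with the 3.43 of Cdkn1a, and a role for it in single genes may remain.

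Another hypothesis is lower activity of LXR, a sterol-sensing nuclear receptor, behind the falls of Srebf1, Abcg5, Abcg8 and Cyp7a1. Of 7 other LXR targets measured, 2 were higher and 2 lower, with a camera p of 0.826. Their median was -0.0729 ± 0.137 (SE over the genes, not over mice). Too few targets that went both ways could be tested, so lower LXR activity may or may not contribute.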
